A study of Carbonactinospora thermoautotrophica with 14 samples.

How the data were processed

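RNA was sequenced from Carbonactinospora thermoautotrophica strain StC, a heat-loving actinobacterium that can grow on carbon monoxide, after 4 days of growth at 60 °C. Per the labels, 5 libraries came from cells on N-FIX solid medium under CO, CO2, N2 and O2 without organic carbon, 5 from cells on R2A agar with glucose and peptone, and 4 from cells on N-FIX medium under CO and CO2 with an ammonium salt. These groups are called N-FIX, R2A and N-FIX+NH4. The design text says that the experiment was done in quadruplicate, while the labels give groups of 5, 5 and 4 libraries, with replicate numbers 1 to 5, 1 to 5 and 2 to 5. The formula of the ammonium salt is written in several ways in the labels, the treatment label calls it organic nitrogen, and the gas mix stated for that group leaves out N2 and O2. The titles number the libraries of a group after the prefix biol, which is taken here to mark biological replicates, and the p-values measure the spread between them.

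Libraries were made from total RNA with the KAPA mRNA HyperPrep kit, per the labels' protocols. That kit captures RNA with poly(A) tails, which most bacterial messenger RNA lacks, so the share of counts in other abundant RNA can be high. Trimmomatic 0.39, Bowtie2 2.3.4.3, SAMtools 0.1.20 and HTSeq 2.0.3 are listed in the submitters' processing notes. Per the file headers, the deposited table holds raw counts per gene made with featureCounts 2.0.3, so the notes and the header name different counting tools. The header's command sets the paired-end option without counting read pairs, which in this version counts reads, not fragments. It sets no strand option and no option for reads that map to several places or overlap several genes. Without strand, reads from a gene and from an overlapping gene on the other strand cannot be told apart. The genome build is not given in the sources used here. The positions are those of the deposited annotation, 1-based, on a sequence named StC_01.

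The deposited table lists 4599 features, 2369 on the plus and 2230 on the minus strand, with a last annotated position of 4728050. Feature lengths ran from 72 to 6186 bp with a median of 765 bp, and 41 lengths were not multiples of 3. A length that is a multiple of 3 does not by itself show that a feature is coding. The files do not pair the feature identifiers with gene names or products, and no annotation with names was used here. The gene lists fixed before the data were examined (carbon fixation pathways, carbon monoxide dehydrogenase, microcompartment, nitrogen assimilation and others) therefore could not be matched, and no list test was run. By the naming rule fixed for this case, at most 2 identifiers that rose and 2 that fell are given per comparison: those with the largest fold change among genes with an adjusted p under 0.05, no overlap between the groups in CPM and a mean of at least 20 CPM in the higher group. Other results are given by position.

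Genes were tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled by TMM, which sets a scaling factor per library so that most genes are centred on no change. Genes with low counts were removed by filterByExpr, which left 4577 of 4599 features. A quasi-likelihood model with the 3 groups was fitted to all 14 libraries, and each comparison was a two-sided F-test with Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values are counts scaled to 1000000 per TMM-scaled library, computed here. The log2 values are differences of fitted log2 expression, also computed here from the deposited counts. Principal components were computed from the log2 CPM of the tested genes. Comparisons that share a group share its chance values. Overlaps of calls were therefore set beside 20 simulations of unchanged groups, beside the overlap of independent lists, and beside the overlap with the shared libraries divided between the comparisons.

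A block was a run of at least 4 features in the order of the annotation that were each called, changed at least 2-fold and moved in the same direction. This rule was chosen after the data were seen, because no gene names were at hand. The number of genes in blocks was compared with 10000 shuffles of the gene order. Shuffling treats neighbouring genes as independent, which they are not. Log2 fold changes of all adjacent pairs correlated with r = 0.646 to 0.713 over the 3 comparisons. A small permutation p therefore shows only that calls cluster along the sequence. Blocks are named here if they were among the 3 in each direction with the largest median log2 fold change and the median of their genes' mean levels was at least 20 CPM. Pairs of features of equal length, with mean counts of at least 50 and counts within a log2 of 0.3 of each other in every library, were searched for, since the counting can divide reads between near-identical copies. The search gave 17 pairs with 34 features.

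Total counts per library ran from 31982909 to 58402753, and the number of features with a count was 4583 to 4594 per library. Chi-square per degree of freedom between libraries of a group was at least 102, so no library repeated another within sampling noise. Whether replicate numbers pair libraries across groups was checked from the correlation of deviations from the group means. Between N-FIX and N-FIX+NH4 these correlations were 0.51, 0.17, 0.10 and 0.29 for numbers 2 to 5, each above the limit of 0.1, so the numbers were taken to pair these libraries. This pairing comes from the data alone, as the labels do not say what a number marks. The limit was not set against chance correlations, so a pairing is possible but not shown. The reported fit does not use it, so its p-values between these groups are unpaired. It called 2273 genes there, against 2210 with a replicate block. N-FIX replicates 2 and 5 correlated best with their own number, while replicate 3 correlated best with number 5 and replicate 4 with number 2.

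The fit was tested on simulated counts in which 200 genes were changed by known amounts. Far more genes were called in the data, so the simulated rates of recovery and of false calls need not apply there. For a simulated N-FIX against R2A comparison of 4573 genes, 77% of genes changed by a log2 of 1 and 100% of those changed by a log2 of 2 were recovered, and 6.3% of calls were false. For N-FIX+NH4 against R2A on 4573 genes, these values were 77%, 100% and 2.2%. For N-FIX against N-FIX+NH4 on 4572 genes, they were 86%, 100% and 3.6%. The block search found 10 of 10 runs of calls planted among 4599 features without other calls. No counts were simulated there, so this checks only the run search and gives no rate of recovery for blocks. Alternatives were other size factors, library totals, no low-count filter, DESeq2 1.42.0, only the compared groups, a replicate block, a fold threshold, the 10 most abundant features left out and each library left out in turn. Thinning every library to the smallest total, leaving out near-identical copies and the block fit with only the compared groups were added after the data were seen. Leaving out structural RNA could not be done, because the table does not state feature types. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for regions and figures.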

Results

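The study measured RNA levels of Carbonactinospora thermoautotrophica StC grown on carbon gases (N-FIX, n = 5), on organic medium (R2A, n = 5) and on carbon gases with ammonium (N-FIX+NH4, n = 4). Its title concerns the presence of both the Calvin cycle and the reductive TCA cycle in this bacterium, along with a compartment that concentrates CO2. Total counts of N-FIX replicates 1 to 5 were 49532389, 33092603, 44388165, 31982909 and 42459172. Those of R2A replicates 1 to 5 were 57259918, 45272057, 47062825, 58402753 and 49210130. Those of N-FIX+NH4 replicates 2 to 5 were 55051141, 55463172, 45132171 and 49712702. N-FIX libraries were shallower in total counts, with a mean of 40291048 ± 7545401 (SD, n = 5) against 51441537 ± 6010966 in R2A (SD, n = 5) and 51339796 ± 4897562 in N-FIX+NH4 (SD, n = 4).

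The libraries separated by growth condition. The first principal component of log2 CPM held 62.7% of the variance and placed the R2A libraries between 44.1 and 54.4, the N-FIX+NH4 libraries between -21.0 and -8.81, and the N-FIX libraries between -42.3 and -35.8. The second component held 20.5% and placed the N-FIX+NH4 libraries between -37.1 and -27.3, below all other libraries. Of 4577 tested genes, 3967 were called in at least 1 of the 3 comparisons, 1067 in all 3 and 610 in none.

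**Figure D1:**
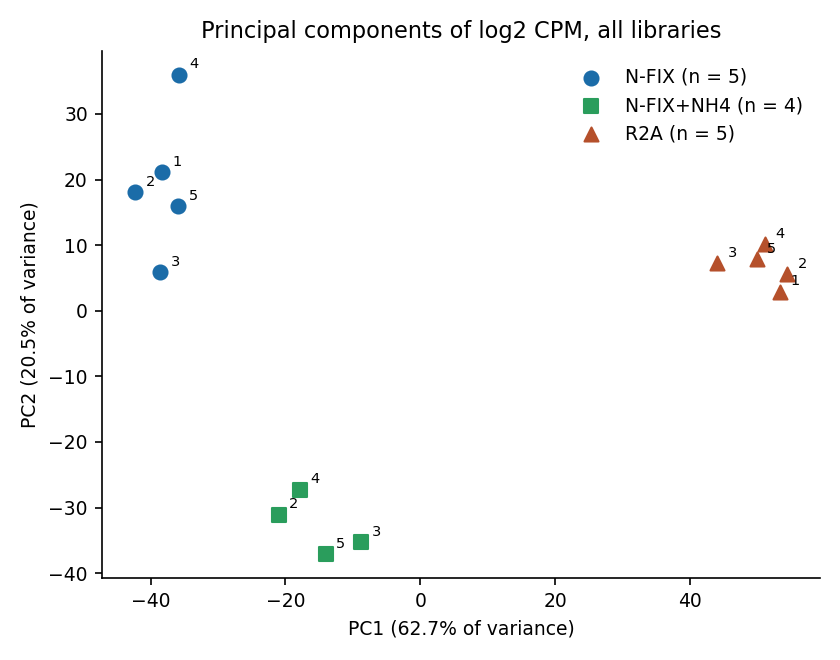
Principal components of log2 CPM for the 14 libraries, with the first component (62.7% of variance) on the x axis and the second (20.5%) on the y axis. Each point is a library, marked by group and numbered by replicate, and the 3 groups occupy separate areas.

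Counts in every library were concentrated in 6 features at 3 places of the sequence, which were picked out after their values were seen. Together these features took 46.3% ± 4.32 of counts in N-FIX (SD, n = 5), 56.5% ± 2.28 in R2A (SD, n = 5) and 59.2% ± 2.81 in N-FIX+NH4 (SD, n = 4). A feature of 3126 bp at 18989 to 22114 and another of the same length at 3749895 to 3753020, each preceded by a feature of 1527 bp, had counts that differed by at most 0.191% in any library. Reads of such copies cannot be assigned to 1 of them, so their counts are uncertain singly, and their sum was 40.6% ± 3.60 of counts in N-FIX, 54.4% ± 2.01 in R2A and 54.3% ± 4.03 in N-FIX+NH4. The pair was lower in N-FIX than in R2A by a log2 of -0.84 (SE 0.16, edgeR adjusted p = 0.000283), and lower than in N-FIX+NH4 by -0.71 (SE 0.17, adjusted p = 0.0031).

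The remaining feature of 3126 bp, on the minus strand at 2443245 to 2446370 beside a feature of 1553 bp, moved in the other direction. It held 4.13% ± 3.22 of counts in N-FIX, with libraries from 0.811% to 8.98%, against 0.394% ± 0.0959 in R2A, with libraries from 0.308% to 0.503%. In N-FIX+NH4 it held 2.68% ± 1.43, with libraries from 0.684% to 4.09%. Its log2 fold change was 2.97 in N-FIX against R2A (SE 0.56, edgeR adjusted p = 0.000228) and 2.61 in N-FIX+NH4 against R2A (SE 0.57, adjusted p = 0.000906). Between N-FIX and N-FIX+NH4 the difference of 0.35 (SE 0.56, adjusted p = 0.62) did not pass the test.

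**Figure D2:**
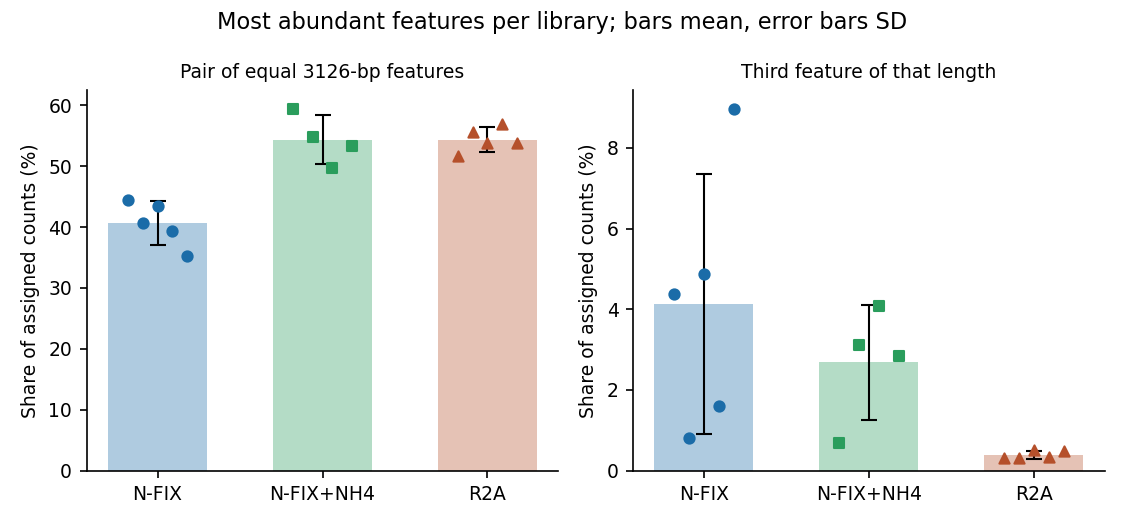
Share of assigned counts in the pair of equal 3126-bp features (left) and in the third feature of that length (right), in percent, for N-FIX, N-FIX+NH4 and R2A. Points are libraries, bars are means and error bars are SD. The third feature lies between 0.811% and 8.98% in N-FIX libraries and between 0.308% and 0.503% in R2A libraries.

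The comparison of N-FIX with R2A sets cells on N-FIX medium under carbon gases beside cells on R2A agar with glucose and peptone. The medium and the sources of carbon and nitrogen differ together, so their effects cannot be separated. The largest rise was in a block of 9 adjacent genes at 3640453 to 3651855, 8 of them on the minus strand. Its summed level was 6919 ± 3980 CPM in N-FIX (SD, n = 5) and 28.2 ± 2.32 CPM in R2A (SD, n = 5), and it took 0.831% ± 0.505 of counts in N-FIX against 0.00247% ± 0.000188 in R2A. The median log2 fold change of its genes was 8.18, with a range from 4.64 to 10.32. In N-FIX+NH4 the summed level was 98.0 ± 43.0 CPM (SD, n = 4). The gene that adjoins the block at 3652054 to 3653208 had a log2 fold change of 0.17 (SE 0.15, edgeR adjusted p = 0.318), which did not pass the test. The gene on the other side, at 3639239 to 3640621 on the plus strand, was called higher, at 0.80 (SE 0.33, adjusted p = 0.0392).

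**Figure D3:**
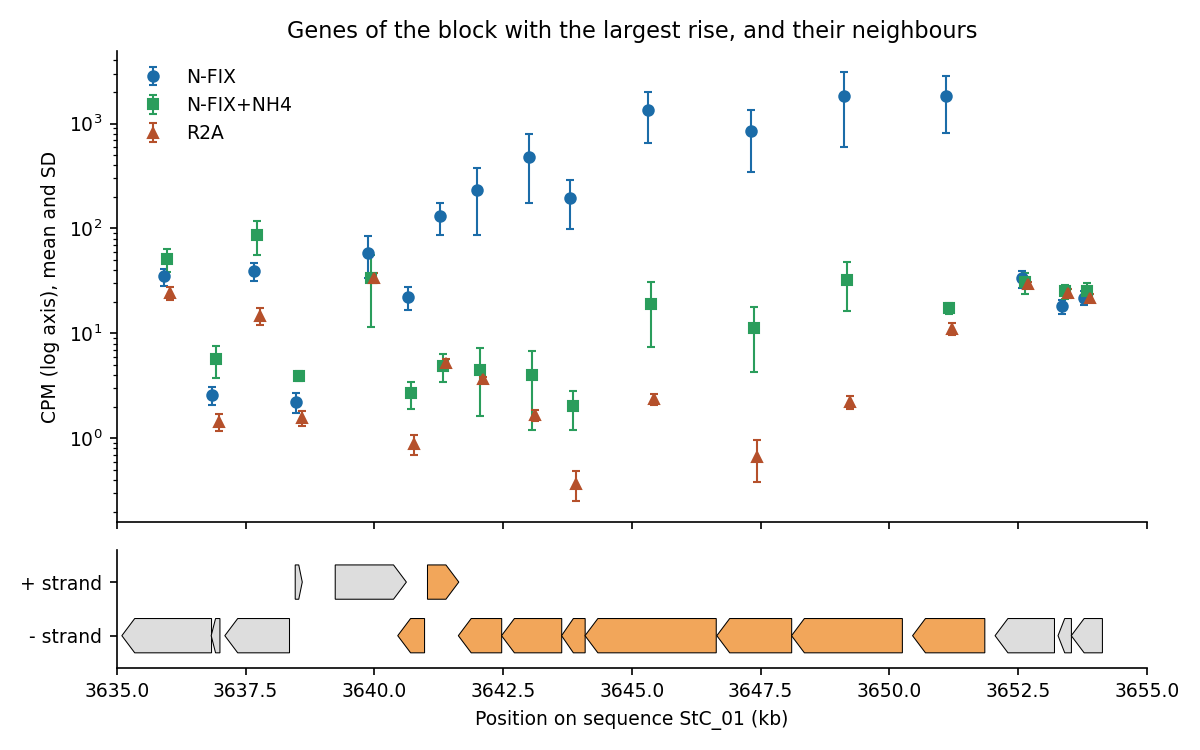
Level of each gene in the block at 3640453 to 3651855 and of its neighbours, as mean CPM with SD on a log axis, against position on sequence StC_01 in kb. Arrows below show the strand and extent of each gene, with the 9 genes of the block in orange. Within the block each N-FIX mean lies above the means of the other groups, from 22.2 CPM to 1847 CPM.

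Within this block, IKOGDBKN_03592 at 3646650 to 3648104 on the minus strand had the largest rise. It stood at 848 ± 505 CPM in N-FIX (SD, n = 5) and 0.668 ± 0.287 CPM in R2A (SD, n = 5), where its counts were 19 to 45 per library. Its log2 fold change was 10.32 (SE 0.63, edgeR adjusted p = 3.59e-09), and all 5 N-FIX libraries lay above all 5 R2A libraries, which the naming rule requires. Its neighbour IKOGDBKN_03593 at 3648101 to 3650254 rose by a log2 of 9.70 (SE 0.56, adjusted p = 2.2e-09), from 2.22 ± 0.303 to 1847 ± 1243 CPM. The first gene of the block, at 3640453 to 3640974 on the minus strand, overlaps that plus-strand gene, so the counts of both are uncertain without strand.

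Other blocks rose in N-FIX over R2A. A block of 5 genes at 507515 to 511136 rose from 365 ± 68.3 to 4791 ± 661 CPM, with a median log2 fold change of 3.34. A block of 5 genes at 4153029 to 4159530 rose from 47.0 ± 3.56 to 355 ± 121 CPM, with a median of 3.88. The longest risen block held 17 genes at 3089371 to 3104725, 15.4 kb long, with a median of 2.87.

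Genes that were lower in N-FIX than in R2A also lay together. A block of 5 genes at 3260236 to 3263017 fell from 4312 ± 750 CPM in R2A to 152.1 ± 102.4 CPM in N-FIX, with a median log2 fold change of -3.64. A block of 8 genes at 1773673 to 1778569 fell from 1348 ± 53.5 to 129 ± 34.4 CPM, with a median of -3.38. A block of 6 genes on the plus strand at 147160 to 152841 fell from 946 ± 78.6 to 80.2 ± 27.8 CPM, with a median of -3.39. The longest fallen block held 17 genes at 383012 to 395011 with a median of -2.03. Of single genes, IKOGDBKN_00648, a feature of 111 bp at 642183 to 642293, stood at 271 ± 102 CPM in R2A and 3.25 ± 1.18 CPM in N-FIX, a log2 fold change of -6.38 (SE 0.34, edgeR adjusted p = 1.02e-09). IKOGDBKN_03605 at 3658434 to 3659048 stood at 525 ± 94.9 CPM in R2A and 10.7 ± 0.758 CPM in N-FIX, a log2 fold change of -5.62 (SE 0.16, adjusted p = 3.79e-12). For both genes all R2A libraries lay above all N-FIX libraries, which the naming rule requires.

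In total, 3235 of 4577 genes were called, 1643 higher and 1592 lower in N-FIX. Of these, 861 were at least 2-fold higher and 807 at least 2-fold lower, and 95 were at least 8-fold higher and 78 at least 8-fold lower. The groups did not overlap in CPM for 2602 genes, 56.8% of those tested, where chance gives 0.794%. The 114 blocks, 57 higher and 57 lower, held 657 genes, against a mean of 34.5 and at most 84 in 10000 shuffles of the gene order (permutation p = 0.0001, the smallest they can give). Here and in the other comparisons, these shuffles show only that calls cluster along the sequence, and they test no single block. With library totals in place of TMM the median log2 fold change of all genes moved from 0.02 to 0.44, and 70.2% of calls were higher in N-FIX instead of 50.8%. Changes are therefore given relative to the bulk of genes.

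**Figure D4:**
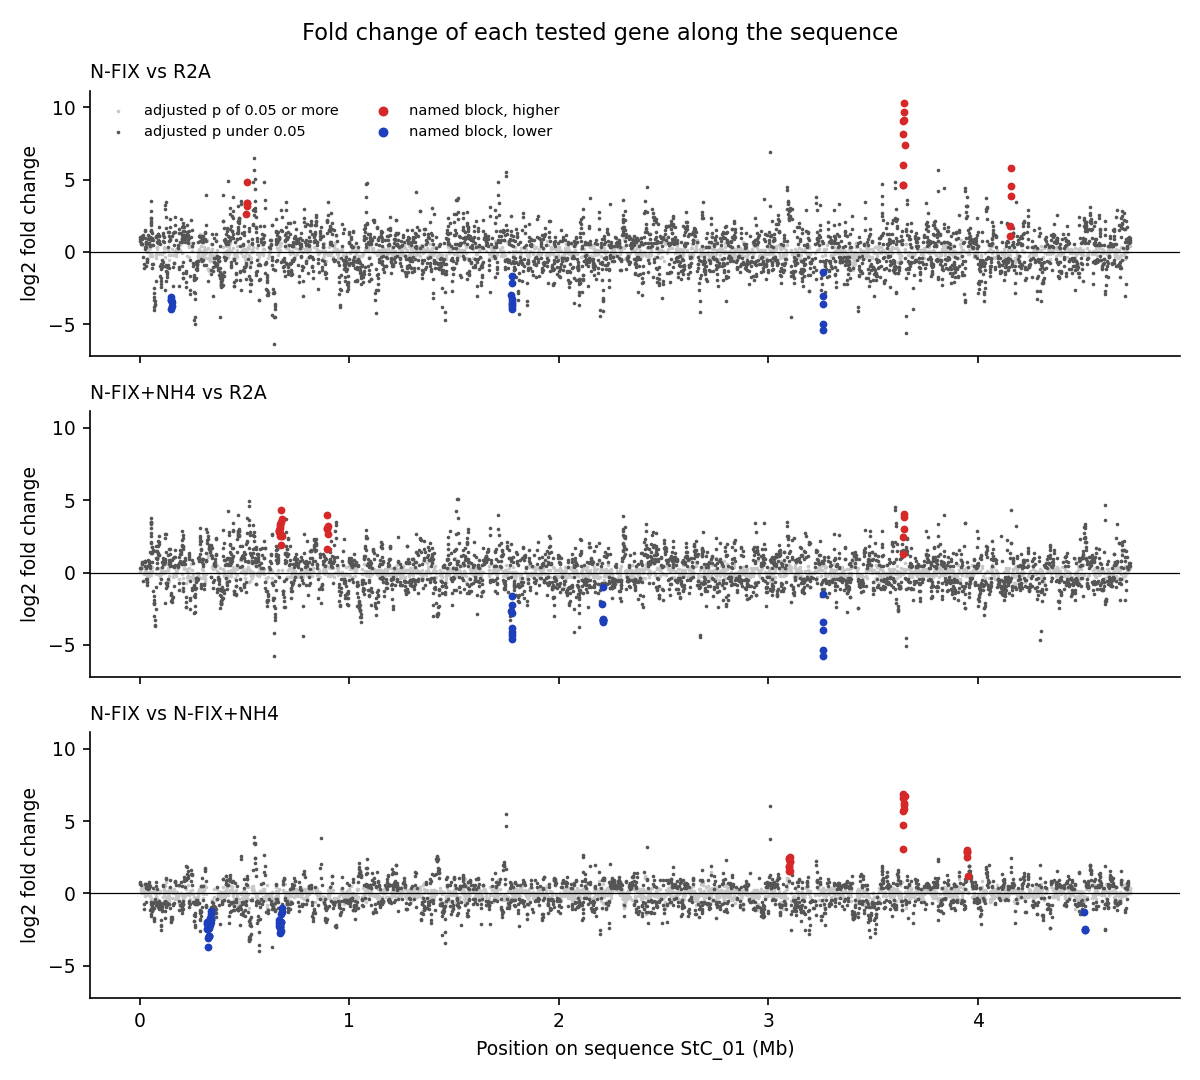
Log2 fold change of each tested gene (y axis) against position on sequence StC_01 in Mb (x axis) for the 3 comparisons. Dark points have an adjusted p under 0.05, and coloured points are genes of the named blocks, red where higher and blue where lower in the first group. In the upper panel the block at 3640453 to 3651855 reaches 10.32.

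The comparison of N-FIX+NH4 with R2A sets gas-grown cells given ammonium beside the same R2A cells, and its conditions cannot be separated either. A block of 6 genes on the plus strand at 890791 to 899140 stood at 2216 ± 1020 CPM (SD, n = 4) against 214 ± 35.5 CPM in R2A (SD, n = 5), with a median log2 fold change of 3.08. All 6 genes were also called higher in N-FIX than in R2A, with a median of 2.18. A block of 14 genes at 663829 to 677584, 13.8 kb long, stood at 2971 ± 453 against 424 ± 88.5 CPM, with a median of 2.93. In N-FIX against R2A, 6 of these 14 genes were called higher, 1 lower and 7 were not called. From the region most raised in N-FIX, a stretch of 5 genes at 3642469 to 3650254 rose from 7.27 ± 0.574 to 68.6 ± 37.6 CPM, with a median of 3.02.

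The blocks that fell furthest were low in both gas-grown groups. The 5 genes at 3260236 to 3263017 stood at 119 ± 41.8 CPM in N-FIX+NH4 (median log2 fold change -3.95) and the 8 genes at 1773673 to 1778569 at 111 ± 12.4 CPM (median -3.32). The 7 genes at 2207711 to 2213450 fell from 1386 ± 62.6 CPM in R2A to 236 ± 58.4 CPM, with a median of -3.26, and 6 of them were called lower in N-FIX too. The 6 genes at 147160 to 152841 fell less, to 273 ± 103 CPM, with a median of -1.70. That this fall was smaller than in N-FIX was tested between the gas-grown groups, where all 6 genes were called lower in N-FIX, with a median of -1.76.

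The genes with the largest rise were the adjoining IKOGDBKN_01492 at 1515635 to 1516711 and IKOGDBKN_01491 at 1515063 to 1515638, both on the plus strand. IKOGDBKN_01492 stood at 215 ± 107 CPM against 6.26 ± 0.969 CPM in R2A (log2 fold change 5.10, SE 0.54, edgeR adjusted p = 1.38e-06). IKOGDBKN_01491 stood at 210 ± 127 against 6.30 ± 1.28 CPM (5.06, SE 0.57, adjusted p = 2.6e-06), and its N-FIX level was 74.5 ± 60.4 CPM. The largest falls were those of IKOGDBKN_00648, from 271 ± 102 to 5.0 ± 1.2 CPM (-5.76, SE 0.36, adjusted p = 2.13e-08), and of IKOGDBKN_03212 at 3261616 to 3262008, from 448 ± 76.9 to 8.42 ± 4.03 CPM (-5.74, SE 0.49, adjusted p = 2.13e-07). IKOGDBKN_03212 is a gene of the fallen block at 3260236 to 3263017.

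In total, 2990 of 4577 genes were called, 1557 higher and 1433 lower in N-FIX+NH4, of which 830 and 619 changed at least 2-fold. The groups did not overlap for 2594 genes, 56.7%, where chance gives 1.59%. The 101 blocks, 59 higher and 42 lower, held 634 genes, against a mean of 22.1 and at most 68 in 10000 shuffles (permutation p = 0.0001, the smallest they can give). With library totals the median log2 fold change of all genes moved from 0.05 to 0.18, and 59.9% of calls were higher in place of 52.1%.

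Genes called in the same direction in both gas-grown groups against R2A numbered 2282, of which 1141 were higher and 1141 lower. A further 96 were called in opposite directions. Simulated unchanged groups, with every library drawn from the R2A mean levels, gave 0 shared calls in each of 20 simulations. Groups without a change are expected to give few calls, so this value does not measure overlap that shared libraries cause between changed groups. Independent lists of these lengths would share 1057. With the R2A libraries divided between the comparisons, the shared calls numbered 1918 and 1973. The first division gave 935 higher and 983 lower, where independent lists would share 446 and 425, and the second gave 960 and 1013, where they would share 421 and 408. Dividing R2A does not remove variation that gas-grown libraries of equal replicate number may share.

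The comparison of N-FIX with N-FIX+NH4 sets gas-grown cells without and with ammonium side by side, and the stated gas mixes differ too, so an effect of ammonium and an effect of N2 or O2 cannot be separated. The 9-gene block at 3640453 to 3651855 again changed most. All 9 genes were higher in N-FIX, with a median log2 fold change of 6.12 and a range from 3.05 to 6.91. In N-FIX+NH4 against R2A, 6 of its 9 genes were called higher and 3 were not called, with a median of 1.60. A block of 5 genes on the plus strand at 3946165 to 3952477 stood at 5190 ± 2287 CPM in N-FIX (SD, n = 5) and 802 ± 179 CPM in N-FIX+NH4 (SD, n = 4), with a median of 2.85, and at 702 ± 51.8 CPM in R2A. A block of 9 genes at 3098144 to 3104725 stood at 874 ± 451 CPM in N-FIX, 185 ± 51.7 CPM in N-FIX+NH4 and 128 ± 16.6 CPM in R2A, with a median of 2.16.

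Other blocks were higher with ammonium. The 14 genes at 663829 to 677584 stood at 585 ± 461 CPM in N-FIX and 2971 ± 453 CPM in N-FIX+NH4 (median log2 fold change -2.13). The longest block held 20 genes at 319331 to 339915, 20.6 kb long, with 379 ± 151 CPM in N-FIX, 2300 ± 930 CPM in N-FIX+NH4 and 768 ± 444 CPM in R2A (median -2.07). The 4 genes at 4508509 to 4511458 stood at 70.8 ± 23.8 CPM in N-FIX, 374 ± 122 CPM in N-FIX+NH4 and 38.7 ± 3.64 CPM in R2A (median -2.49).

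**Figure D5:**
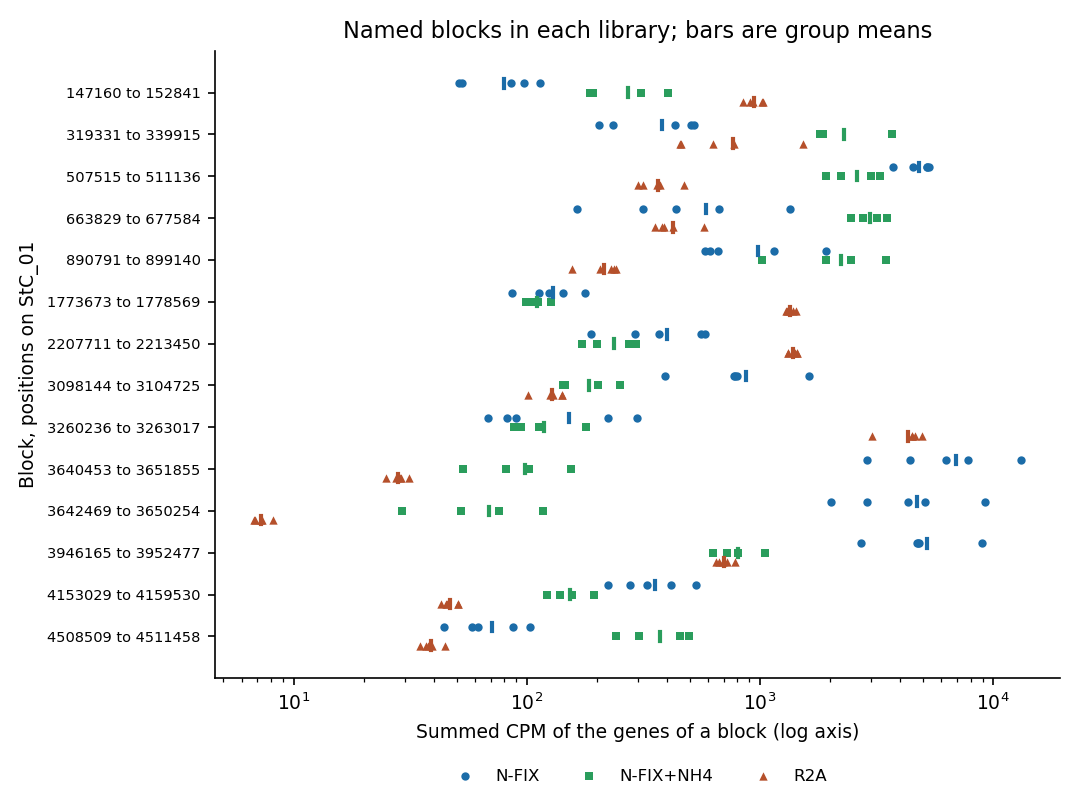
Summed CPM (x axis, log scale) of the genes of each named block (y axis, positions on StC_01) in every library. Points are libraries, coloured and shaped by group, and short bars are group means. At 3640453 to 3651855 the N-FIX libraries lie between 2867 and 13209 CPM and the R2A libraries between 24.8 and 31.2 CPM.

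Of single genes, IKOGDBKN_03589 at 3642469 to 3643638 stood at 480 ± 307 CPM in N-FIX and 4.0 ± 2.8 CPM in N-FIX+NH4 (log2 fold change 6.91, SE 0.62, edgeR adjusted p = 2.04e-06). IKOGDBKN_03594 at 3650452 to 3651855 stood at 1825 ± 1019 and 17.3 ± 2.18 CPM (6.72, SE 0.43, adjusted p = 1.36e-07). Both lie in the 9-gene block. IKOGDBKN_00585 at 566252 to 567115 was lower in N-FIX, at 1.33 ± 0.403 against 20.94 ± 15.97 CPM (-3.97, SE 0.58, adjusted p = 7.76e-05). Without N-FIX+NH4 replicate 5 its mean in that group was 12.97 ± 1.07 CPM (SD, n = 3), below the naming limit of 20 CPM, and its log2 fold change was -3.28 (adjusted p = 0.000254). IKOGDBKN_00327 at 326315 to 327607, within the 20-gene block, stood at 80.7 ± 52.9 against 1074 ± 471 CPM (-3.73, SE 0.70, adjusted p = 0.000556), and its level in R2A was 187 ± 200 CPM, or 100.4 ± 59.9 CPM without replicate 2 (SD, n = 4).

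In total, 2273 of 4577 genes were called, 1057 higher and 1216 lower in N-FIX, of which 299 and 478 changed at least 2-fold. The groups did not overlap for 1607 genes, 35.1%, where chance gives 1.59%. The 53 blocks, 21 higher and 32 lower, held 353 genes, against a mean of 2.25 and at most 18 in 10000 shuffles (permutation p = 0.0001, the smallest they can give). With library totals the median log2 fold change of all genes moved from -0.05 to 0.25, and 73.5% of calls were higher in N-FIX in place of 46.5%.

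Genes called higher in N-FIX than in both other groups numbered 692, and those called lower than in both 695. Independent lists would share 379 and 423, and with the N-FIX libraries divided between the comparisons the counts were 560 and 560 for higher and 523 and 521 for lower, where independent lists from the divided libraries would share 292 and 283 for higher and 322 and 285 for lower. Genes called higher in N-FIX+NH4 than in both other groups numbered 493 and those called lower 369. Independent lists would share 414 and 331, and dividing the N-FIX+NH4 libraries gave 282 and 356 for higher and 229 and 241 for lower, where independent lists from the divided libraries would share 233 and 302 for higher and 196 and 229 for lower. Simulated unchanged groups gave at most 1 such gene in 20 simulations of each pattern, which again does not measure overlap through shared libraries. Of these 4 counts, 3 moved by over 1.5 times with library totals, to 1259 higher and 296 lower in N-FIX and 307 higher in N-FIX+NH4.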

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

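In the tests of this part, the comparison of the third abundant feature with the equal pair was chosen after its levels had been seen, and the splits of the libraries were planned. In 90 groups of values, a library stood far apart from the others of its group 10 times, by a gap to its nearest neighbour that was large for the range of the group. Chance gives about 4.5 such cases if the groups of values are independent, which they are not, since some are adjoining genes or a gene and its block. Of these, 5 were in R2A, 5 in N-FIX+NH4 and 0 in N-FIX.

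Several of the cases belong to the ammonium group. IKOGDBKN_00585 stood at 44.9 CPM in N-FIX+NH4 replicate 5, against 11.9 to 14.1 CPM in the other libraries of the group. The 20-gene block at 319331 to 339915 stood at 3695 CPM in the same replicate, against 1803 to 1857 CPM. In N-FIX+NH4 replicate 3, IKOGDBKN_01491 stood at 399.5 CPM and IKOGDBKN_01492 at 374 CPM, against 128 to 159 CPM and 142 to 174.5 CPM. IKOGDBKN_03212 stood at 14.4 CPM in N-FIX+NH4 replicate 2, against 5.89 to 7.34 CPM.

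The other cases were in R2A. IKOGDBKN_00327 stood at 531.5 CPM in R2A replicate 2, against 48.9 to 169 CPM, and IKOGDBKN_00585 at 34.9 CPM in the same library, against 5.53 to 13.6 CPM. R2A replicate 3 held 312 CPM of IKOGDBKN_03212, against 467 to 497 CPM, and 3016 CPM of the block at 3260236 to 3263017 that contains it, against 4470 to 4952 CPM. IKOGDBKN_01491 stood at 8.58 CPM in R2A replicate 1, against 5.59 to 5.83 CPM.

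Whether an arbitrary grouping of the libraries could give as many called genes was tested on 100 splits per comparison, the real one included. For N-FIX against R2A, 1 of 100 splits, the real one, reached 3235 called genes, and the highest other split gave 222. For N-FIX+NH4 against R2A, 1 of 100 reached 2990, and the highest other gave 2382. For N-FIX against N-FIX+NH4, 1 of 100 reached 2273, and the highest other gave 1705. Those highest splits of 9 libraries moved 4 libraries of each group, which puts all but 1 library of the larger group on the other side. They therefore part the conditions with 1 library out of place. Among the 11 drawn splits of N-FIX and N-FIX+NH4 that part as many pairs of equal replicate number as the real one, the highest other gave 824, and these splits are too few for a share under 0.05. For both comparisons with R2A, an arbitrary grouping would rarely give as many calls. This restates that the libraries part by condition and does not test how many calls are right. For N-FIX against N-FIX+NH4, the real split also stood alone among 100, but these splits leave a possible pairing aside. Those that keep it are too few to decide.

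The third feature of 3126 bp at 2443245 to 2446370 was raised in gas-grown cells while the equal pair of that length was not. If its counts were a constant share of the pair's reads assigned to it in error, its log2 fold change in N-FIX against R2A should equal that of the pair. It differed from the pair by 3.81 (SE 0.58, taking the 2 values as independent), which argues against a constant share for the whole rise. A share that varies between libraries was not tested. The ratio of the third feature to the mean of the pair varied 12.7-fold among N-FIX libraries, 7.14-fold in N-FIX+NH4 and 1.69-fold in R2A. Replicate 2 held the lowest share of the third feature in each group, at 0.811%, 0.684% and 0.308%. A response to the growth condition may be the reason, as a hypothesis, and a difference in RNA capture between libraries was not tested and stays open.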

How the results depend on the processing

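The added settings were thinning, leaving out near-identical copies and the replicate block with only the compared groups, and they and the block rule were chosen after the data were seen. Across 24 settings besides the reported one, all 288 values of named genes kept their direction and an adjusted p under 0.05. The naming rule picks large changes without overlap between the groups, so this says little about other calls. Of 432 block medians, 430 moved by less than the spread between libraries, and 2 moved under library totals: in N-FIX against R2A, the block at 1773673 to 1778569 to -2.95 and that at 507515 to 511136 to 3.75. The features of 3126 bp kept their side of the threshold under each setting that held them, and called values kept their direction. Under library totals the fall of the pair in N-FIX against R2A shrank from -0.84 to -0.42. Of 267 counts of genes, 261 stayed within 1.5 times. Totals hide a change of genes under library totals, where 2631 of 3235, 2723 of 2990 and 1672 of 2273 calls were shared with the reported ones (0 in the opposite direction), and lower calls fell from 1592 to 988 for N-FIX against R2A and from 1216 to 615 for N-FIX against N-FIX+NH4. The 6 others were the counts with at least a 2-fold change, 1668 for N-FIX against R2A, 1449 for N-FIX+NH4 against R2A and 777 for N-FIX against N-FIX+NH4, which are lower by construction, and 3 counts under library totals: 1259 genes higher and 296 lower in N-FIX than in both other groups, and 307 higher in N-FIX+NH4 than in both. The cause of the last 3 follows from the median shifts of 0.44, 0.18 and 0.25 that library totals leave in the 3 comparisons. DESeq2 called 3308, 3050 and 2381 genes, thinning to the smallest total gave 3222, 2968 and 2247, and leaving out the 10 most abundant features gave 3224, 2995 and 2266. Unequal library totals and those features therefore did not set the counts. Features other than the 6 abundant ones held 53.75% of counts in N-FIX, 43.5% in R2A and 40.78% in N-FIX+NH4. N-FIX had the lowest mean total, 40291048, but the highest share outside the 6 features. Its lower totals therefore do not by themselves mean fewer counts in the other features. Thinning to equal totals does not make their depth equal, so an effect of that depth was not tested. With each library left out in turn, the calls ranged from 3113 to 3305, from 2822 to 3045 and from 1973 to 2279, and the genes in blocks from 632 to 674, from 577 to 641 and from 297 to 384. With the replicate block the counts were 3244, 2966 and 2210, and with only the compared groups as well 3111, 2878 and 1977. The block changed no call of a named gene. Correlations of libraries with equal numbers ran from -0.29 to 0.11 in N-FIX against R2A and from -0.18 to 0.07 in N-FIX+NH4 against R2A, not all above the limit of 0.1, so the numbers were not taken to pair those libraries. Not every library correlated best with its own number there, as also in N-FIX against N-FIX+NH4. Leaving out structural RNA and the gene list tests were not run, because the table does not give feature types or names. At a log2 of 1, simulated recovery was 77%, 77% and 86%, so some 2-fold changes can be missed.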

Other observations

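Further blocks of at least 13 genes changed, a length chosen after their values were seen. A block of 14 genes on the minus strand at 1041733 to 1057172, 15.4 kb long, was lower in N-FIX+NH4 than in R2A by a median log2 of -2.50. It was also lower than in N-FIX, with a median of 1.40 for N-FIX against N-FIX+NH4. Within it, 7 genes at 1049363 to 1057172 formed a block that was lower in N-FIX than in R2A, with a median of -1.49. A block of 13 genes at 1413183 to 1429650 was higher in N-FIX than in N-FIX+NH4, with a median of 1.73. Of these, 12 genes at 1414011 to 1429650 were lower in N-FIX+NH4 than in R2A, with a median of -2.58. In N-FIX against R2A there was no block of either direction at these positions. A block of 13 genes on the plus strand at 3955140 to 3969082 was also higher in N-FIX than in N-FIX+NH4, with a median of 1.52. It was part of no block in the comparisons with R2A. A block of 13 genes on the minus strand at 465354 to 475793 was higher in N-FIX than in R2A by a median of 2.03, and with 1 more gene at its start (464515) it was higher in N-FIX+NH4 than in R2A by 2.71. A block of 17 genes at 2304119 to 2317832, 16 of them on the plus strand, was higher in N-FIX+NH4 than in R2A by 2.07 at a low level, with a median of 1.27 CPM over the genes' mean levels. A block of 13 genes at 2092395 to 2101387 was lower in N-FIX than in R2A, with a median of -2.04, as was a block of 13 genes at 256255 to 267186, with a median of -1.94. Blocks of 13 genes at 4506779 to 4516653 (median 2.41), 2643141 to 2654978 (1.52) and 326315 to 338709 (1.69) were higher in N-FIX+NH4 than in R2A. The first and the last of these overlap blocks described for N-FIX against N-FIX+NH4.

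The tests on the sequence ends below were chosen after the result was seen, and those on neighbouring genes and on position were planned. The hypothesis that neighbouring genes change together because unstranded counting mixes the reads of overlapping genes was tested on adjacent pairs of the same strand that do not overlap. Their log2 fold changes in N-FIX against R2A correlated across genes with r = 0.639 over 2356 pairs, against at most 0.047 in 1000 shuffles of the genes, which argues against that explanation for the whole pattern. Such pairs cannot show mixing between strands, so it may still add to the pattern. Across genes, which are not independent replicates, r was 0.901 for the 836 overlapping pairs of the same strand, 0.574 for 681 convergent and 0.343 for 682 divergent pairs. In N-FIX against N-FIX+NH4, convergent pairs (r = 0.695) and non-overlapping pairs of the same strand (r = 0.698) were close. Convergent pairs lay above divergent ones there (r = 0.405) and in N-FIX+NH4 against R2A (r = 0.553 against 0.367). Overlapping pairs of opposite strands were not taken apart, so mixing between strands in such pairs was not tested.

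The hypothesis that gene dosage between the ends and the middle of the sequence shapes the fold changes was tested by fitting a wave of 1 cycle to the medians of 91 bins. In N-FIX against R2A the amplitude was 0.0735 (log2), within the 0.121 below which 95% of shuffled bins lay (permutation p = 0.336). The bin medians themselves ran from -0.83 to 0.67, so a wave of this size does not account for them.

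The features at the start and the end of the sequence match each other. From 473 to 12705, 10 features in a row had the lengths and strands of 10 features from 4714792 to 4727024 at a constant offset of 4714319 bp, a stretch of 12.2 kb. Their counts differed by at most 1.31-fold in any library. These values are consistent with the hypothesis that the ends of the assembled sequence repeat each other, as a circular chromosome cut open with an overlap would give. A true repeat at both ends of a linear chromosome gives the same counts, and the sequence itself was not used here.

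The lengths of the abundant features (1527 or 1553 bp beside 3126 bp) and their share of counts resemble those of ribosomal RNA operons. The deposited table does not state feature types, so this remains a hypothesis without a test. If it holds, the difference of 3.81 (log2) between the third feature and the pair may reflect operons used unequally between growth conditions, which differences in RNA capture could also give.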
